A study of Danio rerio with 8 samples.

How the data were processed

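The series holds 8 zebrafish samples in 4 groups. RNA-seq and ATAC-seq were each done on embryos given SU5402, an inhibitor of fibroblast growth factor (FGF) receptors, and on control embryos given the solvent DMSO, with 2 samples per group. Per the labels' protocols, SU5402 was present at 20 µM from early cleavage onward and RNA was taken at the dome stage, a blastula stage reached soon after zygotic transcription begins. The 4 ATAC-seq samples were not analysed here. Nothing in the labels says whether replicates came from separate clutches, so the p-values measure only the spread between these samples, which may be technical.

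The RNA-seq data were used as a table of the authors' own comparison, with 33843 loci. Per the submitters' processing notes, the tools were TopHat2, Picard, Cufflinks and Cuffdiff and the genome build was Zv9 (danRer7). Their versions and settings are not given in the sources used here. Per the file headers, the table holds 1 FPKM value per condition, so the authors' FPKM pools both replicates and no replicate value, count or library size could be recovered from it. FPKM scales a locus to its length and to the library, so the values are relative to the rest of each condition and a change in total RNA per embryo would be hidden. The deposited log2 fold change compares the 2 conditions, and the deposited score that Cuffdiff calls its test statistic was read but not used. The deposited p-value and q-value were taken as the authors gave them. The q-value decides the authors' own call, which marks a locus as different at a q of at most 0.05. The smallest p-value in the table was 5e-05 and was held by 108 loci.

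Of the loci, 12757 had been tested, 21085 were marked as not tested and 1 as having too little data. The lowest FPKM that a tested locus reached in its higher condition was 0.947. There were 3861 loci with no gene name and 494 with several names joined. Of the 25400 distinct symbols, 14349 were also in the reference table of current names, and the symbols printed here are those of the authors' table, many of them older (ntla, chd, oep). A locus is an assembled region and can hold more than 1 row: 27.1% of the tested loci and 20.4% of the called ones shared their region with another row, and reads may then be split between neighbours. Several starts in the file were 0, so 1 was added to every start and coordinates are given 1-based on Zv9. Depth per sample is unknown, so no counting interval is given, and a value of 0 is described as listed at 0.

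The columns were checked against each other. The deposited log2 fold change was within 0.001 of the ratio of the FPKM values for all but 1 of the 12715 tested loci with a finite ratio. A Benjamini-Hochberg adjustment of the deposited p-values over the 12757 tested loci gave larger values than the deposited q at the threshold. At the largest called p of 0.0151, the deposited q-value was 0.04996, while the adjusted value over this table was 0.268. That adjustment was therefore added, after the data were seen, as a second and stricter reading of each call, and is named the table-wide adjustment. No test across replicates was run, because the table gives no value per replicate.

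A total of 28 gene lists had been fixed before the data were examined, as had the main threshold, the rule for named genes and most alternatives. The lists cover FGF feedback genes and targets, FGF ligands and receptors, immediate early genes, early neural genes, organizer genes and BMP antagonists, the BMP pathway and ventral genes, the Nodal pathway, mesoderm, endoderm, the yolk syncytial layer, the enveloping layer and epidermis, Wnt targets, Notch, retinoic acid, germ plasm, oocyte transcripts, the first zygotic transcripts, pluripotency, cell movement and adhesion, stress, xenobiotic response, the cell cycle, other receptor tyrosine kinases, later differentiation, housekeeping, cytosolic and mitochondrial ribosomal proteins, and Hox genes. Another list, of ribosome biogenesis genes, was added after the data were seen. A member counts as measured when it was tested and reached 1 FPKM in its higher condition. For each list, members called higher and lower were counted by the authors' q, by the table-wide adjustment and by an adjustment over the list alone. The median log2 change of a list was placed among 10000 random lists of the same size matched on mean FPKM in 20 bins (seed 1), which describes these pooled values and is no test across embryos.

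Genes were named by a rule. It took the 10 largest rises and 10 largest falls among called genes with a gene symbol and at least 1 FPKM in the lower condition, up to 3 called members per list and direction, a fixed set of FGF, neural and BMP genes whatever their values, and up to 3 called genes per direction that were listed at 0 in 1 condition. Genes named outside it were chosen after their values were seen: foxd3, foxd5, ca9, dusp4, spred2a, sox11a, flh, mdm2, dact1, rgma, ngfr, prickle1b, gas1b, foxb1.2, snrnp70 and the ribosome biogenesis genes. So were axin2, lef1 and elavl3. Some genes that the rule takes are not reported here. The alternatives tried were other q thresholds, a minimum fold, FPKM minimums, other adjustments, centring, 1 row per symbol, pseudocounts, means in place of medians and unmatched random lists.

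The work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The adjustment and the random lists were tested on simulated data for SU5402 against control over 10933 genes. Every gene was given normal error of the same chosen size, independent between genes and not estimated from these data. The rates that follow therefore check the procedure and do not give the sensitivity of the authors' calls. Of 100 genes simulated at a log2 change of 2, 99 were called, of 100 at a log2 change of 1, 29 were called, and of 10733 unchanged genes 6 were called. Of 100 lists of 20 genes lowered by 0.5, 100 fell under percentile 5, and of 100 unchanged lists 9 fell under percentile 5 or over percentile 95.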

Results

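To ask which transcripts of the early zebrafish embryo depend on FGF signalling at the onset of zygotic transcription and neural induction, RNA from dome-stage embryos was compared between SU5402 treatment and a DMSO control. SU5402 blocks the kinase activity of FGF receptors and was present at 20 µM. Each condition had 2 RNA-seq samples, pooled by the authors into 1 FPKM value per locus, so values below carry no replicate error. At least 1 FPKM was reached by 14654 loci in control and 14795 in SU5402 embryos, and the median FPKM of the 12757 tested loci was 9.94 and 10.3. The median log2 change of the 13788 loci at 1 FPKM or more in both conditions was 0.04.

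Among called genes with at least 1 FPKM in both conditions, the 10 largest falls in SU5402 embryos included the organizer transcript chd and the FGF feedback transcript dusp6. In the authors' deposited table, chd (chordin), a secreted BMP antagonist of the dorsal organizer, fell 13.2-fold from 14.8 to 1.13 FPKM (q = 0.000383). The Wnt regulator dact2 fell from 11.5 to 1.07 FPKM, and dusp6, an ERK phosphatase induced by FGF, fell 8.53-fold from 18.2 to 2.13 FPKM. The BMP-responsive gene id1 fell from 204 to 30.4 FPKM and the mesodermal T-box gene ntla (brachyury) from 20.3 to 3.25 FPKM. The other large falls by the same rule were amotl2a (21.1 to 3.59 FPKM), tph1b (4.52 to 1.005), efna1b (9.43 to 2.25), atp1b1a (38.3 to 10.3) and morc3b (8.85 to 2.56). Among rises, the T-box gene tbx16 went up 4.23-fold from 634 to 2679.9 FPKM, setb from 648 to 3287 FPKM, and nudc, which acts in nuclear migration, from 332 to 1381 FPKM. The selenoprotein gene sepw1 rose from 60.5 to 685 FPKM, DTWD2 from 28.3 to 209, TPRX1 from 153 to 777, cmc2 from 27.3 to 127, phc2b from 286 to 1230.1, ate1 from 4.92 to 18.6 and hps1 from 1.55 to 5.68 FPKM.

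In total, the authors' deposited table called 720 of the 12757 tested loci (5.64%), 457 of them higher and 263 lower in SU5402. With the table-wide adjustment, 210 loci passed, 127 higher and 83 lower. Of the genes in the preceding paragraph, sepw1, TPRX1, ate1 and hps1 did not pass it, with adjusted p between 0.0703 and 0.200 from the authors' p, and the other 16 did. With a pseudocount of 1 FPKM, the log2 change of chd was -2.90 in place of -3.72, that of dact2 -2.60 in place of -3.43 and that of tph1b -1.46 in place of -2.17. The median fold was 1.77 for loci called higher and 1.96 for loci called lower. On Zv9, chd lay at chromosome 15 from 46135867 to 46173294, dusp6 at chromosome 25 from 18813588 to 18817793, id1 at chromosome 11 from 19124535 to 19125635, ntla at chromosome 19 from 30633857 to 30637924 and tbx16 at chromosome 8 from 54012015 to 54031716. DTWD2, TPRX1 and hps1 shared their locus with another row of the table.

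**Figure D1:**
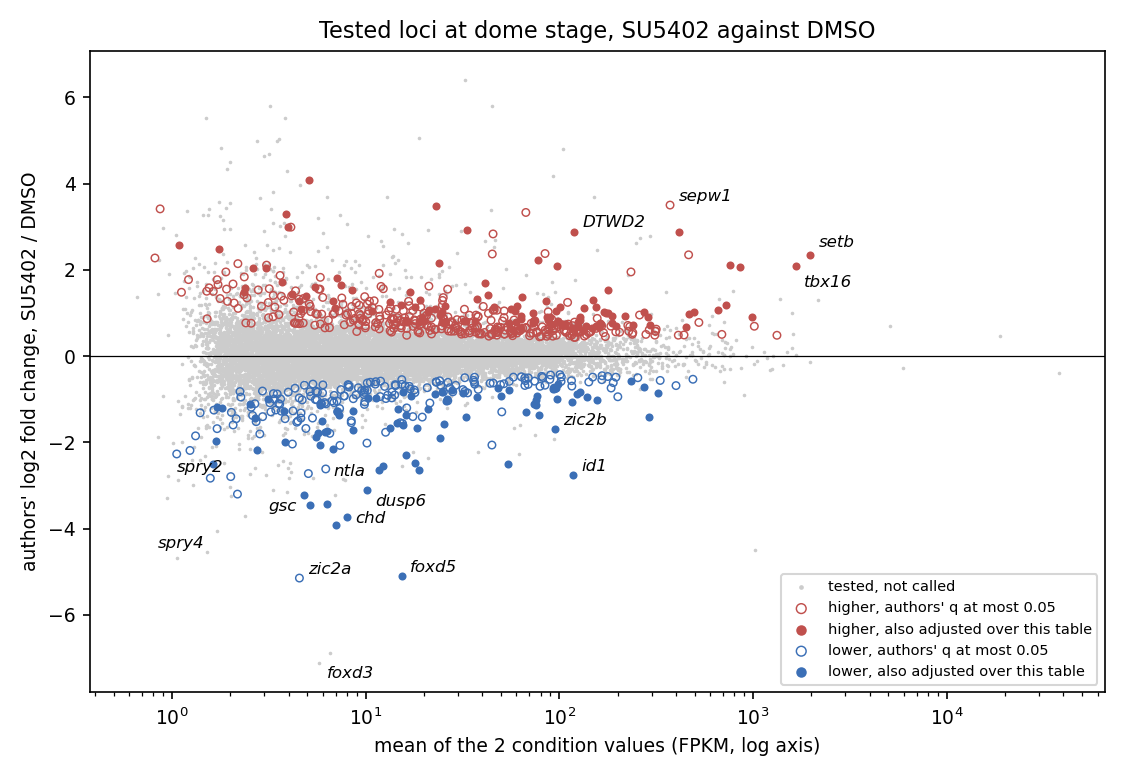
Each point is a tested locus with FPKM above 0 in both conditions, placed by the mean of its 2 condition values (FPKM, log axis) and by the authors' log2 fold change of SU5402 over DMSO. Open coloured points were called by the authors' q and filled ones also passed the table-wide adjustment; chd, dusp6 and gsc lie among the lowest filled points, while foxd3 and spry4 lie far below 0 without a call.

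Of 22 measured FGF feedback genes and targets, the authors' deposited table called 8 lower and 3 higher, and 11 were not called. Besides dusp6 and ntla, the ETS factor gene etv4, a transcriptional effector of FGF, fell 3.17-fold from 20.3 to 6.41 FPKM, and the FGF antagonist spry2 fell from 3.52 to 0.508 FPKM. The phosphatase gene dusp4 fell from 12.2 to 5.03 FPKM. The 3 called higher were tbx16, fgf3 (3.10 to 6.15 FPKM) and spred2b (3.40 to 5.71 FPKM). The paralog of the last, spred2a, was called lower (1.75 to 0.364 FPKM) and did not pass the table-wide adjustment. The feedback gene spry4 had 2.92 FPKM in control and 0.125 in SU5402 but was not called in the authors' deposited table (q = 0.0523), nor was etv5b at 68.9 and 39.6 FPKM (q = 0.0750). The antagonist il17rd (22.2 and 20.2 FPKM) and the ligand gene fgf8a (5.06 and 5.27 FPKM) were not called either. The list's median log2 change was -0.59, and 0 of 10000 matched random lists had a median as low; over the 19 members at 5 FPKM or more it was -0.26, at percentile 0.22. A pseudocount of 1 FPKM gave spry2 a log2 change of -1.58 in place of -2.79 and spry4 -1.80 in place of -4.55. With the table-wide adjustment 4 members were lower (dusp6, ntla, etv4 and dusp4) and 1 higher (tbx16); adjusted over the list alone, 10 were lower and 3 higher.

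Of 7 measured FGF ligands, receptors and adaptors, the authors' deposited table called the receptor gene fgfr4 lower (43.0 to 29.2 FPKM) and fgf3 and the adaptor gene frs2b (18.01 to 27.6 FPKM) higher. The receptor gene fgfr1a had 17.8 FPKM in control and 23.1 in SU5402 and was not called. Those 3 calls were lost with the table-wide adjustment and kept adjusted over the list alone, and the list's median of 0.06 lay at percentile 61.5. Among 9 measured immediate early genes, which ERK signalling can induce within minutes, fos was called higher (3.43 to 6.997 FPKM) and none lower. That call was lost both with the table-wide adjustment and adjusted over the list alone, and the list's median of -0.03 lay at percentile 38.2.

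Of 15 measured organizer genes and BMP antagonists, the authors' deposited table called 5 lower and 1 higher, 9 were not called, and the list had a median of -0.53 that 0 of 10000 matched random lists reached. Beside chd, the organizer homeobox gene gsc (goosecoid) fell 10.97-fold from 9.503 to 0.866 FPKM, sp5l, a zinc finger gene downstream of Wnt, fell from 2.77 to 0.389 FPKM, and foxa3 fell from 31.8 to 17.9 FPKM. The notochord homeobox gene flh went down from 55.2 to 35.9 FPKM. The 1 member called higher, szl (sizzled), is a BMP-induced feedback inhibitor of chordin cleavage expressed ventrally, and rose 2.93-fold from 2.91 to 8.53 FPKM. Under the table-wide adjustment, chd, gsc and foxa3 were lower and no member was higher; adjusted over the list alone the counts were 5 lower and 1 higher. With a pseudocount of 1 FPKM, the log2 change of gsc was -2.49 in place of -3.46 and that of sp5l -1.44 in place of -2.83.

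In the BMP pathway and ventral list, 18 of 21 measured members were not called in the authors' deposited table. Only id1 was called lower, by 6.72-fold, while szl and klf2a (31.8 to 46.0 FPKM) were called higher. The ligand genes bmp2b (24.9 FPKM in control, 19.0 in SU5402) and bmp7a (22.6 and 23.6 FPKM) were not called, and bmp4, under 1 FPKM in both conditions, was not tested. The list's median of 0.04 lay at percentile 48.3 of matched random lists. With the table-wide adjustment id1 alone passed, and adjusted over the list alone 1 member was lower and 1 higher.

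Of 18 measured early neural genes, the authors' deposited table called 5 lower and 2 higher, and 11 were not called. The zinc finger gene zic2a fell from 8.85 to 0.250 FPKM and its paralog zic2b from 145 to 44.9 FPKM, a fall of 3.24-fold at much higher abundance. The homeobox gene irx1b fell from 3.66 to 1.70 FPKM, the SoxC gene sox11a from 130.1 to 65.3 FPKM, and cyp26a1, which degrades retinoic acid, from 41.3 to 22.7 FPKM. The homeobox gene otx1a rose from 2.59 to 6.47 FPKM and gmnn (geminin), a regulator of replication and neural fate, from 776 to 1254 FPKM. The pan-neural gene sox3 was not called at 68.2 and 56.5 FPKM, and sox2 and otx2, both under 1 FPKM, were not tested. The list's median of -0.10 lay at percentile 6.89 of matched random lists, and over the 14 members at 5 FPKM or more it was -0.13, at percentile 4.68. A pseudocount of 1 FPKM gave zic2a a log2 change of -2.98 in place of -5.15. With the table-wide adjustment zic2b, sox11a and cyp26a1 remained lower and no member higher; adjusted over the list alone, 5 were lower and 2 higher.

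Among 12 measured pluripotency genes, the Nodal co-receptor gene oep (161 to 87.3 FPKM) and foxh1 (60.3 to 36.2 FPKM), which encodes a DNA-binding partner of Smad proteins in Nodal signalling, were called lower in the authors' deposited table, none was higher, and both calls held under each adjustment. The median of this list was 0.05, at percentile 47.3. The stem cell factor gene foxd3 was listed at 11.4 FPKM in control and 0.0820 in SU5402 with no call in the authors' deposited table (q = 0.392). In contrast foxd5, a forkhead gene of the early dorsal embryo outside the lists, fell 34.2-fold from 29.8 to 0.871 FPKM and passed the table-wide adjustment. With a pseudocount of 1 FPKM, foxd5 had a log2 change of -4.04 in place of -5.10 and foxd3 of -3.52 in place of -7.12.

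In the mesoderm list, the T-box genes ntla and tbx16 were called in opposite directions. The authors' deposited table called 5 of 12 measured members lower, among them ntla, osr1 (3.77 to 1.45 FPKM) and snai1b (10.1 to 6.31 FPKM), and tbx16 higher. The median was -0.22 at percentile 1.06, but -0.09 at percentile 13.9 over the 10 members at 5 FPKM or more. With the table-wide adjustment ntla was lower and tbx16 higher, and adjusted over the list alone 5 were lower and 3 higher. In the Nodal pathway list, 4 of 15 measured members were called lower (gsc, ntla, oep and foxh1) and 2 higher. The 2 were dvr1 (Vg1), a maternal Nodal partner, from 349 to 553 FPKM, and the Nodal antagonist lft2 from 6.93 to 12.5 FPKM. All 4 falls and the rise of dvr1 passed the table-wide adjustment, adjusted over the list alone the counts were 4 and 2, and the median of -0.22 lay at percentile 1.15. Of 9 measured endoderm genes, the chemokine receptor gene cxcr4a (49.4 to 25.8 FPKM) and foxa3 were called lower under each adjustment. None was called higher, and the list's median was 0.09 at percentile 65.9.

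In the cell movement and adhesion list, 22 members were measured. In the authors' deposited table, cxcr4a, the chemokine gene cxcl12a (10.2 to 6.21 FPKM) and snai1b were called lower and none higher. Only cxcr4a passed the table-wide adjustment and the adjustment over the list alone, while the list median of -0.26 lay at percentile 0.03. The Wnt target list also holds ligands, receptors and other pathway genes, and 16 of its members were measured. Of these, sp5l and the Wnt antagonist genes sfrp1a (43.2 to 24.0 FPKM) and notum1a (7.06 to 4.02 FPKM) were called lower and none higher. The other 13 were not called, among them the targets axin2 (8.88 and 7.43 FPKM) and lef1 (21.8 and 23.7 FPKM). The list's median was -0.19 at percentile 1.67. None of the 3 called genes passed the table-wide adjustment, and all 3 passed adjusted over the list alone. Among 5 measured retinoic acid genes cyp26a1 was the 1 call, held under each adjustment, with a median of -0.10 at percentile 19.7. No call was made among 7 measured Notch genes (median 0.06, percentile 56.2), 3 other receptor tyrosine kinase genes (median -0.06, percentile 41.4) or 5 xenobiotic response genes (median 0.07, percentile 60.0), also when adjusted over each list alone. None of 43 Hox genes was measured.

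Of 8 measured yolk syncytial layer genes, apoeb, which encodes an apolipoprotein, rose 2.02-fold from 328 to 661 FPKM in the authors' deposited table under each adjustment, and the list median was -0.07 at percentile 26.1. In the enveloping layer and epidermis list, 2 of 17 measured members were called higher, krt8 (69.2 to 106 FPKM) among them, and cldne (33.95 to 20.4 FPKM) was called lower, with a median of 0.16 at percentile 84.0. These calls were lost with the table-wide adjustment and kept adjusted over the list alone.

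Among 27 measured oocyte transcripts, the authors' deposited table called zar1 (16.8 to 26.9 FPKM), wee2 (158 to 233 FPKM) and the linker histone gene h1m (1108 to 1549 FPKM) higher and zp2.3 (12.6 to 7.05 FPKM) and btg4 (122.6 to 81.6 FPKM) lower, and 22 were not called. None passed the table-wide adjustment, all 5 passed adjusted over the list alone, and the median of 0.03 lay at percentile 39.8. In the germ plasm list tdrd6 (5.68 to 11.3 FPKM) was the 1 call among 16 measured, lost under both other adjustments, with a median of -0.04 at percentile 19.3. Of 29 measured genes of the first zygotic list, 5 were called lower (chd, dusp6, osr1, hspb1 and cldne) and 3 higher (tbx16, apoeb and blf, the last from 251 to 375 FPKM), with a median of -0.12 at percentile 0.80. The table-wide adjustment left 3 lower and 2 higher, and the adjustment over the list alone 5 and 3. Of its measured members, 19 stood outside the FGF, organizer, neural, BMP, Nodal and mesoderm lists.

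In the stress list, the cell cycle inhibitor gene cdkn1a (5.67 to 12.9 FPKM), phlda3 (4.76 to 9.83 FPKM), gadd45aa (2.28 to 6.01 FPKM) and mdm2 (57.7 to 118 FPKM) were called higher in the authors' deposited table, and the small heat shock gene hspb1 fell from 183 to 95.4 FPKM. The other 14 of 19 measured members were not called. The 4 rises were lost with the table-wide adjustment and kept adjusted over the list alone, while the fall of hspb1 held under both. The median of 0.08 lay at percentile 68.6. Of matched random lists, 1.22% had as many members called higher and 37.1% as many called lower. Of 29 measured cell cycle genes, ccne2 (20.5 to 8.81 FPKM), ccnd1 (208 to 103 FPKM) and plk1 (119.5 to 76.6 FPKM) were called lower under each adjustment. None was called higher, and the list's median was -0.07 at percentile 3.85. Of 3 measured later differentiation genes, lmo2 (2.26 to 6.44 FPKM) was called higher, a call lost with the table-wide adjustment. Adjusted over the list alone 2 were higher, and the median was 1.21 at percentile 99.7. That median is the value of 1 gene, elavl3 (0.943 and 2.18 FPKM), which was not called in the authors' deposited table (q = 0.0848). Of 32 genes of this list that were found, only 3 were measured.

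Among 17 measured housekeeping genes, actb1 fell from 282 to 189 FPKM under each adjustment and no other was called in the authors' deposited table, with a median of -0.08 at percentile 4.99. Cytosolic ribosomal protein genes had a median of -0.18 over 76 measured members, and 0 of 10000 matched random lists had a median as low. Within that list single genes went both ways: rps4x fell from 423 to 159 FPKM, rpl12 from 414 to 229.9 and rps19 from 48.1 to 28.2, while rplp1 rose from 86.5 to 213 FPKM and rpl26 from 122 to 205. In all 3 members were called lower and 5 higher, against 2 and 3 with the table-wide adjustment and 2 and 4 adjusted over the list alone. Mitochondrial ribosomal protein genes had a median of 0.22 over 61 measured members, at percentile 99.99. Of these mrpl12 was called higher (28.8 to 57.3 FPKM) and mrpl36 (6.02 to 3.07 FPKM) and mrpl13 (18.4 to 9.86 FPKM) lower in the authors' deposited table, and no call passed either other adjustment.

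A few called loci were listed at 0 in 1 condition, so no fold is given for them. There were 14 such loci at 0 in control and 6 at 0 in SU5402, and 17 of these 20 had no gene name. The named ones were mir430a-11 (0 and 124 FPKM), a copy of the microRNA that clears maternal transcripts, at chromosome 4 from 28008950 to 28009079, si:dkey-193l3.9 (0 and 3.33 FPKM) and the acylphosphatase gene acyp1 (3.27 and 0 FPKM). In the authors' deposited table mir430a-11 had q = 0.0353 and did not pass the table-wide adjustment, and the other 2 did. The mir430a-11 value is scaled to a short locus, and how reads were assigned among the copies of this microRNA is not known.

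The authors' deposited table gave p of at most 0.05 to 1418 of the tested loci, against 637.9 that chance alone would give. Its q was 0.0649 times the table-wide adjusted value at the smallest p and 0.187 times at the largest called p, so no constant factor linked them. A q of 0.04996 at p = 0.0151 in the authors' deposited table corresponds to 30.2% of tests at or below that p, whereas 5.64% of this table's tests were. Numbering of loci ran to 35868, with 2025 numbers absent from the deposited table. Counting each of those as a test at the smallest p would give an adjusted value of 0.0813 at that point.

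**Figure D2:**
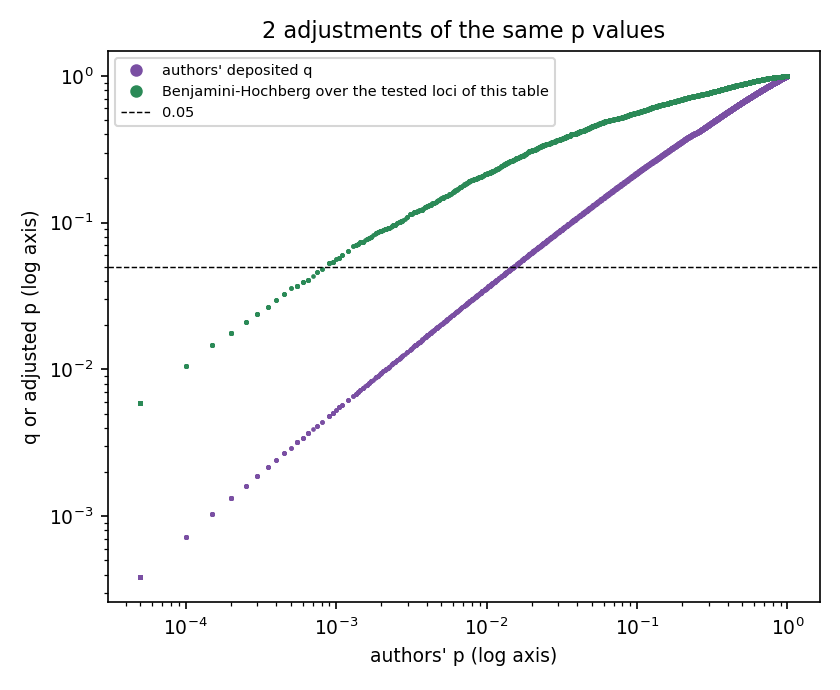
For each tested locus, the authors' p (log axis) against the authors' deposited q and against the Benjamini-Hochberg adjusted value over the tested loci of this table (log axis). The dashed line at 0.05 is reached by the deposited q at a p of 0.0151 and by the table-wide adjustment at a p of 0.0008.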

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

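The table-wide adjustment and the removal of shared or unnamed loci were chosen after the data were seen, and the other settings before. Among the 720 calls (457 higher, 263 lower), a q of at most 0.01 left 297 (184 and 113), a q of at most 0.1 gave 1166 (738 and 428), and a minimum of 2-fold left 291 (164 and 127). A Benjamini-Hochberg adjustment over this table left 210 (127 and 83), the same number whether over all tested loci or those at 1 FPKM or more. Bonferroni left 0 (0 and 0), because the smallest p of 5e-05 cannot pass it over 12757 loci; 1418 had an unadjusted p of at most 0.05. An FPKM minimum of 1 removed no call, and an FPKM minimum of 5, centring, 1 row per symbol and leaving out shared or unnamed loci each kept the counts within 1.5 times. The excess of higher over lower calls was present under each setting that left calls. With the table-wide adjustment the FGF list kept 4 lower and 1 higher calls, the neural list 3 and 0, the organizer list 3 and 0, the mesoderm list 1 lower, and the BMP list 0 higher; the stricter threshold is the cause of these losses. The mean log2 change of the neural list was -0.72 against a median of -0.10, and that of the BMP list -0.11 against 0.04. Among other low members, the neural list held zic2a at -5.15, and the BMP list held id1 at -2.75. Such values move a mean more than a median. No mean without these genes was computed, so how much of either gap they account for is not known. Mean and median also differed in sign for pluripotency (-0.68 and 0.05), endoderm (-0.04 and 0.09), oocyte (-0.03 and 0.03), germ plasm (0.01 and -0.04), xenobiotic (-0.02 and 0.07) and yolk syncytial layer genes (0.07 and -0.07). Over members at 5 FPKM or more, the FGF median was -0.26 (percentile 0.22), the organizer median -0.58 (percentile 0), the neural -0.13 (percentile 4.68), the BMP 0.04 (percentile 47.2) and the mesoderm -0.09 (percentile 13.9, against 1.06). A total of 107 named genes with a finite fold were compared in this way, with spred2a, axin2, lef1 and elavl3 not among them. With a pseudocount of 1 FPKM, 14 moved by over 1.5-fold, all towards 0 (chd, dact2, tph1b, spry2, spry4, zic2a, gsc, sp5l, bmp4, foxd5, foxd3, ca9, foxb1.2 and ngfr). A pseudocount of 0.1 moved 2 (spry4 and foxd3) and centring 0, and no sign changed. No paired analysis was possible because the table pools the replicates. For that reason the replicate block, leaving out each replicate, and the settings for replicate values or counts were not run, and no other splits of the samples could be made. Depth is unknown, so genes near 1 FPKM carry an error that cannot be given.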

Other observations

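Ribosome biogenesis genes act in the nucleolus to process ribosomal RNA and assemble ribosomal subunits. Of 118 measured genes with such names, the authors' deposited table called 19 higher and 0 lower in SU5402 embryos, 99 were not called, and 9 of the rises passed the table-wide adjustment. Examples are exosc7, a subunit of the RNA exosome (37.4 to 83.8 FPKM), rrp1 (63.2 to 130.2 FPKM), the small subunit factors krr1 (24.0 to 42.0 FPKM) and utp11l (79.6 to 134 FPKM), rbm28 (54.1 to 92.8 FPKM), nop16 (104 to 169 FPKM) and the pseudouridine synthase gene dkc1 (151 to 243 FPKM). The list median was 0.17 at percentile 99.87 of matched random lists, and adjusted over the list alone 15 were higher and 0 lower. The list was put together after several of these genes had been seen among the calls, so its count is not independent evidence. The loci of rrp1 and dkc1 also held other rows. So did those of prickle1b, zic2a, gmnn, blf, tdrd6, rpl12, plk1, notum1a, lmo2 and si:dkey-193l3.9, named in other paragraphs.

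Other falls lay outside the lists. In the authors' deposited table these were ca9, a carbonic anhydrase gene (8.68 to 0.926 FPKM), the forkhead gene foxb1.2 (3.93 to 0.428 FPKM), ngfr (2.69 to 0.690 FPKM), rgma, a BMP co-receptor gene (8.76 to 3.11 FPKM), the planar polarity gene prickle1b (25.4 to 9.62 FPKM), dact1 (10.1 to 4.16 FPKM) and the Hedgehog co-receptor gene gas1b (5.40 to 2.22 FPKM). All but foxb1.2 and prickle1b passed the table-wide adjustment. A pseudocount of 1 FPKM gave a log2 change of -2.33 in place of -3.23 for ca9, -1.79 in place of -3.20 for foxb1.2 and -1.13 in place of -1.96 for ngfr. A total of 53 tested loci, 20 of them named, differed at least 8-fold in FPKM between conditions and were not called. Called loci were more often higher than lower among abundant transcripts, with 10.3% higher and 3.84% lower in the highest of 10 bins of mean FPKM against 2.27% and 1.57% in the lowest. For snrnp70 the authors' deposited table lists 256 and 142 FPKM, a log2 ratio of -0.85, beside a deposited log2 change of -0.44.

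In the weighing that follows, the test on the remaining ribosome biogenesis genes was set before its result was seen, and the tests of scaling, abundance and embryo age after. The first pattern is the lower median of FGF feedback genes and targets and of organizer genes, each with called members in both directions. A scaling difference between conditions would move all genes alike and is argued against by the FGF median, which lay -0.62 from the median of matched random lists. Noise that is independent between genes of this abundance is argued against by the FGF and organizer medians, each at percentile 0 of those lists. The scaling and noise readings of the FGF list use the same comparison with random lists, so they are not independent of each other. A difference carried by 1 sample is not excluded. Treated embryos younger at collection cannot be told apart from an effect of FGF receptor inhibition, which the design names and which stays open: 19 first zygotic transcripts outside the pattern lists had a median of -0.03 at percentile 15.7. Oocyte transcripts, which that explanation was taken to place above percentile 95, lay at percentile 39.8 with members going both ways. That bound was set after the value had been seen, so no conclusion is drawn from it.

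The second pattern is a higher median of ribosome biogenesis and mitochondrial ribosomal protein genes beside a lower median of cytosolic ribosomal protein genes. The called members do not follow these medians in the last 2 lists, with 1 higher and 2 lower mitochondrial and 5 higher and 3 lower cytosolic genes. Chance among the ribosome biogenesis genes already seen stays open: the 109 members that did not pass the table-wide adjustment had a median of 0.14 at percentile 98.7 of matched random lists of genes that did not pass either, but 10 of them were called higher and the list was drawn up after calls had been seen. A change that follows abundance alone is argued against by both ribosomal protein lists. The mitochondrial genes lay at percentile 99.99 of lists matched on mean FPKM and the cytosolic ones at percentile 0. The members of both lists were fixed before the data were examined, but the bounds were set after these percentiles were seen. The same medians define the pattern, so they are no independent support for it. Differences in RNA selection or transcript length were not tested, and without values per replicate a difference carried by 1 sample may underlie the percentile of 99.99.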
